A study of Mus musculus with 4 samples.

How the data were processed

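Single-cell RNA libraries were made from the vestibular ganglion, the cluster of sensory neuron cell bodies that connects the balance organs of the inner ear with the brainstem, of wild-type C57BL/6J mice aged 4 weeks. Per the labels' protocols, ganglia of 4 mice were pooled for each preparation, dissociated with collagenase and papain, and loaded on a droplet instrument (10x Genomics Chromium, 3' chemistry) that gives the transcripts of each droplet a common barcode. Libraries were grouped by the sex given in their titles, as 3 male libraries (replicates 1 to 3) and 1 female library (replicate 4). Each library pools its own mice, so differences between libraries hold both biological and preparation effects.

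The submitters' processing notes name Cell Ranger, with no version, and the genome build mm10; the annotation release is not given in the sources used here. For each library, 2 deposited text files were used: the unfiltered list of barcodes, which names the columns of a gene-by-barcode matrix, and the list of genes, which names its rows. The matrix itself, which holds the transcript counts, was not used here. Expression levels, cell types, cell numbers and the total count per library were therefore not analysed, and the comparisons of neuron subtypes, of neurons with other cells, of cell class shares and of male with female expression that were planned before the data were examined were not made. No gene is named by its expression, and sequencing depth is unknown.

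Each barcode line held 16 bases and a constant suffix. Barcodes were compared between libraries by exact match. For a pair of libraries, the size of a common pool from which both lists would be independent draws was estimated as the product of the list sizes divided by the number of shared barcodes (Lincoln-Petersen). The expected overlap of a pair used the median estimate of the other 5 pairs. Shares are given with exact Clopper-Pearson intervals at 95% confidence, which cover counting error only and treat barcodes as independent. The interval of a ratio is that of the shared number divided by the expected number, taken as fixed. It leaves out the spread of the pool estimates. On simulated independent lists of the real sizes, the largest error of the pool estimate was 0.0572%, and on simulated lists with paired barcode forms it was 0.0565% after merging. In the latter, a second form was added only beside a listed first form, so merging gave back independent lists. A second form listed without the first was not simulated. With 1 female library, no test between the sexes was run.

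Gene identifiers were matched to GENCODE release M21, an annotation of GRCm38, the assembly that mm10 names. Of 32285 identifiers, 32235 (99.8%) were found, and 50 were not; 31502 of those found had the same symbol in M21, which is not known to be the release the authors used; coordinates and gene types come from M21 and count from 1. Gene symbols are those of the deposited lists. The 5 lists of neuronal and dissociation genes and 19 lists of cell type markers that were fixed before the data were examined were looked up by symbol. A listed gene was called overlapped where the gene body of another listed gene shared bases with it on the same strand. Not every member of these lists is reported here by name.

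The alternatives were other pool size estimates, matching with up to 1 base difference on 20000 randomly drawn barcodes per pair, leaving out each library, counting symbols in place of identifiers, and, added after the data were seen, merging barcodes that form complementary pairs. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.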

Results

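The series profiled the vestibular ganglion of young wild-type mice in 4 droplet-based single-cell libraries, 3 from males and 1 from females, to resolve the types of vestibular ganglion neurons. The data used here were the barcode list and the gene list of each library. These lists name the barcodes that form the columns of the count matrix and the genes that could be counted, and hold no transcript count. They give no expression level for any gene, no cell type and no number of cells, and the sex labels were not checked against sex-linked transcripts.

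The gene list defined which genes could be counted, not which transcripts the libraries held. It was identical in all 4 libraries and held 32285 gene identifiers under 32245 symbols, with 38 symbols standing on more than 1 line. Of the 22028 protein-coding genes in GENCODE M21, 21702 were listed (98.5%), as were 5605 of 5854 long intergenic non-coding RNAs (95.7%). The authors' annotation release is not given in the sources used here, so the unlisted genes of these types can be differences between releases. Listing also went by gene type. Antisense genes were listed almost in full (2955 of 2959), while other types were absent or nearly absent as a whole, which differences between releases alone would not give. Of 9941 processed pseudogenes only 1 was listed. None of the 2207 microRNA genes, 1507 small nucleolar RNA genes or 354 ribosomal RNA genes of M21 was listed. Mitochondrial transcripts were represented by 13 protein-coding genes, and neither the 2 mitochondrial ribosomal RNAs nor the 22 mitochondrial transfer RNAs were listed. The Y chromosome contributed 725 genes and the X chromosome 1084.

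All 121 genes of the 24 fixed lists stood on exactly 1 line of the gene list. The list for calyx-bearing and type I neurons had 15 of 15 members listed. Among them were Calb2, which encodes the calcium-binding protein calretinin (chromosome 8, 110137502 to 110168210, minus strand), Calb1, which encodes calbindin (chromosome 4, 15881264 to 15908064, plus strand), and Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050, plus strand). The list for bouton and small neurons had 12 of 12 listed, including Prph, which encodes the intermediate filament peripherin (chromosome 15, 99055174 to 99058978, plus strand). The pan-neuronal list had 10 of 10 listed, including the synaptic gene Snap25 (chromosome 2, 136713453 to 136782428, plus strand) and the vesicular glutamate transporter gene Slc17a6 (chromosome 7, 51622006 to 51671119, plus strand). The glutamate receptor list had 9 of 9 and the immediate early and dissociation list 8 of 8. In the lists for surrounding cells, all 5 markers of myelinating Schwann cells, all 5 of satellite glia, all 5 of fibroblasts and all 5 of macrophages were listed. The remaining marker lists were complete as well. Presence in the list says that a gene could be counted, not that it was detected. Since 98.5% of the protein-coding genes of M21 were listed, complete lists are no result about these cell types.

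Of the 121 genes, 9 overlapped another listed gene on the same strand, and 112 did not. Whole gene bodies were compared, introns included. The share over all listed genes was not computed, so 9 of 121 cannot be called high or low. Reads from a shared stretch can be ambiguous between 2 genes. None of the 15 calyx and type I genes was overlapped. Among the bouton and small neuron genes, Ntrk3, the neurotrophin 3 receptor gene, overlapped Gm39038. In the pan-neuronal list, Rbfox3 overlapped Gm11749, Syt1 overlapped Gm5136, and Gata3 overlapped 9230102O04Rik. Grik2, a kainate receptor gene, overlapped 2 listed genes, Gm26543 and Gm47018. In the marker lists, L1cam overlapped Arhgap4, and the macrophage marker Cx3cr1 overlapped 3 genes (Csrnp1, Gorasp1 and Xirp1) across its annotated span. Chat, the acetylcholine synthesis gene used as a motor neuron marker, overlapped Slc18a3, the vesicular acetylcholine transporter gene that lies within the same locus.

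The number of barcodes in the female library lay within the range of the male libraries. Male replicate 1 listed 2388470 barcodes, male replicate 2 listed 3283635 and male replicate 3 listed 2433640, giving a male mean of 2701915 ± 504290 (SD, n = 3). The female library listed 3133427. With 1 female library, the difference between the sexes was not tested. The lists are unfiltered, so these numbers include barcodes without a cell. They count barcode sequences, not droplets, and do not measure cell yield or depth.

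**Figure D1:**
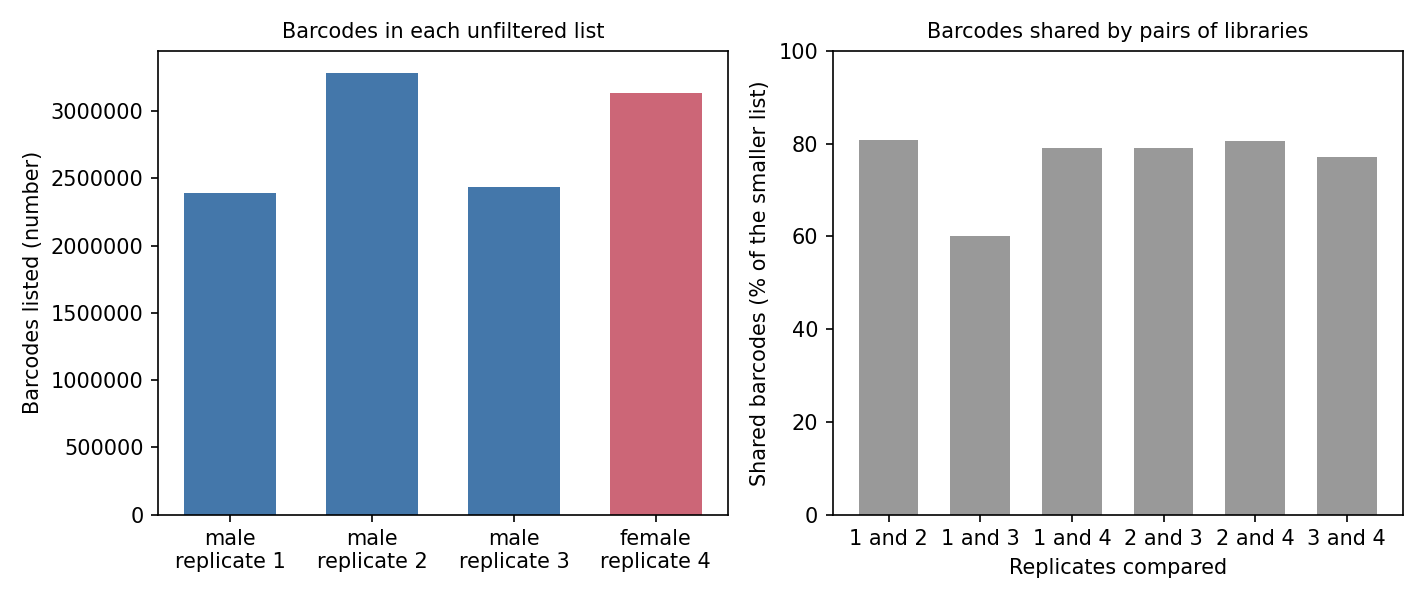
Left, barcodes in the unfiltered list of each library (number of barcodes), with 1 bar per library (blue, male; red, female). Right, barcodes shared by each of the 6 pairs of libraries as a percentage of the smaller list of the pair; male replicates 1 and 3, the smallest lists, shared 60.2%, and the other pairs shared 77.1% to 80.8%.

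The 4 lists together held 4179009 different barcodes. Of these, 658958 (15.8%) were in 1 list, 960680 (23.0%) in 2, 1578630 (37.8%) in 3 and 980741 (23.5%) in all 4. The share of a list found in no other list was 3.91% (95% interval 3.89 to 3.94) in male replicate 1, 7.72% (7.69 to 7.74) in male replicate 2, 5.85% (5.82 to 5.88) in male replicate 3 and 5.42% (5.39 to 5.44) in the female library.

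Each pair's overlap was set against the overlap expected from the pool size that the other pairs gave, so the ratios compare the pairs with each other and do not test whether the lists are independent draws. Across the whole set, 15.8% of barcodes were in 1 list where independent draws from 1 pool predict 7.67%. Of the 6 pairs, male replicates 1 and 2 shared 1930295 barcodes, 1.00 times the expected number (95% interval 0.999 to 1.00). Male replicates 1 and 3 shared 1436963, and their ratio of observed to expected was 1.004 (1.003 to 1.005). The largest departure upwards was between male replicate 1 and the female library, with 1887122 shared and a ratio of 1.025 (1.024 to 1.025). The largest downwards was between male replicates 2 and 3, with 1925628 shared and a ratio of 0.979 (0.978 to 0.980). The female library shared 2523873 barcodes with male replicate 2, a ratio of 0.996 (0.996 to 0.997), and 1877135 with male replicate 3, a ratio of 1.00 (0.999 to 1.00). After barcodes that form complementary pairs were merged, a setting added after the data were seen, the ratio was 1.001 (1.0001 to 1.001) for male replicate 1 and the female library and 1.00 (0.999 to 1.00) for male replicates 2 and 3. For male replicates 1 and 3 it moved further from 1, to 1.006 (1.005 to 1.007), and for male replicate 2 and the female library it was 0.997 (0.996 to 0.997).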

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

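With 3 male libraries, leaving 1 out always moves their mean number of barcodes by less than 1 SD. Removing the constant suffix cannot move it. The gene list held 32245 entries by symbol. The median ratio of observed to expected overlap lies near 1 by construction, since each pair is set against the others. It was 1.029 with the union as the pool. With the pool taken from a single pair and applied to the other pairs it was 0.996 from replicates 1 and 3, 0.976 from replicates 1 and 4, 1.022 from replicates 2 and 3, and 1.004 from replicates 2 and 4. Leaving out one library gave 0.990 to 1.008. The median shared percentage, 79.1%, became 77.1% to 80.5% when 1 library was left out. It was 84.8% when paired barcode forms were merged, a setting chosen after the data were seen. Counting 1 base difference as shared gave 82.2%. That value is 79.1% plus the rise of the median in the drawn barcodes, not a median over the full lists. For single pairs, 35 of 48 alternatives, merging included, moved the value beyond its counting interval, and their ratios ranged from 0.956 to 1.054. The ratio of male replicate 1 and the female library was 1.020 to 1.054 over the pool sizes tried. This pair gave the lowest pool estimate, so any other pool size had to put its ratio above 1. Male replicates 2 and 3 gave the highest estimate, so only the union as the pool could raise their ratio above 1 (1.007). Neither result tests stability. The planned expression alternatives were not run, because no transcript counts were used. Depth is unknown, so a barcode missing from a list cannot be separated from one that was present and not sequenced.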

Other observations

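Both tests in this part were chosen after the result was seen. The union of the 4 lists was 2.86% larger than the median pool estimate of 4062709 barcodes (range over pairs 3965878 to 4149911), which independent draws from 1 pool would not give, and barcodes found in 1 list made up 15.8% of the union where independent draws predict 7.67%. In 38.2% of the barcodes of the union, the sequence with its bases 8 and 9 (counted from 1 at the 5′ end) replaced by their complements was also in the union. The same exchange at the 14 other adjacent pairs of positions gave 0% to 17.3%. It was 0% at positions 7 and 8 and at positions 9 and 10, and 11.8% to 17.3% elsewhere. What random sequences would give was not computed, so these values are not a chance level. Barcodes found in 1 list had such a partner in 75.7% of cases, against 30.2% to 33.2% of those found in 2, 3 or 4 lists. A candidate explanation is that each bead carries 2 forms of its barcode, the second being captured less often. After partners were merged, the union held 3380994 barcodes and exceeded the median pool estimate by 0.324%, against 3.14% to 3.79% after merging at the other adjacent positions where any partner was found, and the pool estimates of the 6 pairs spread over 0.972% where they had spread over 4.64%. The cause of the rest of the excess stays open. Independent lists cannot have a union above their pool, so an excess would need a pool estimate that is too low. In the simulations with paired forms the error of that estimate was at most 0.0565%, so the rest is larger than the sampling error simulated. A second form listed without the first was not simulated.

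Single-base errors in barcodes were considered as a second explanation. The partners merged above differ at 2 bases, so merging them does not join barcodes that differ at 1 base. It still took the excess of the union over the median pool estimate from 2.86% to 0.324%. These values argue against single-base errors as the main source of that excess. For the rest of the excess, single-base errors stay open. A neighbour at 1 base difference in the union was present for 289031 barcodes found in 1 list (43.9%) and for 14.9% of those found in 2 or more. The 43.9% lies between a bound for errors as the main source (most barcodes found in 1 list) and a bound against. Both bounds were set after the result was seen. The bound against lay below the 14.9% of barcodes found in 2 or more lists, so it could hardly be met. The neighbour test therefore cannot decide. It was run on the union before merging, so it does not address the rest of the excess. The read counts per barcode that would separate errors from rare forms were not used. Within a library, both forms were listed for 7.96% of merged barcodes in male replicate 1, 13.5% in male replicate 2, 9.74% in male replicate 3 and 10.7% in the female library. The 2 longest lists had the 2 highest percentages. No biological explanation was tested, because barcode lists carry no information on the cells.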
